A study of Mus musculus with 18 samples.

How the data were processed

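Gene expression was measured on single-channel Agilent mouse arrays in macrophages grown from bone marrow. Per the labels, marrow cells of male C57BL/6J mice aged 8 weeks were cultured for 7 days with macrophage colony stimulating factor, the growth factor that drives marrow cells into macrophages, and 200 ng of RNA was labelled for each array. The mice were wild type or carried a knockout of PHD3, the protein encoded by Egln3. PHD3 is an oxygen-dependent prolyl hydroxylase that marks the alpha subunits of hypoxia-inducible factor (HIF) for degradation. The labels give an oxygen concentration of 1 or 20 without a unit, and a feeding state of control or starved. Whether starvation was applied to the cultured cells or to the mice is not given in the sources used here. The field for the label names biotin while the labelling protocol names Cy3, and the scanner files hold 1 colour channel.

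Per the file headers, the deposited scanner files hold the intensity of each spot after background subtraction and detrending within the array by Agilent Feature Extraction 10.7.3.1, with no normalization between arrays, and an array design built on mm9. The series value table deposited by the authors holds log2 values. Its columns contain nearly the same sorted values, differing by at most 0.0110, as quantile normalization gives. The submitters' processing notes name limma, with no version. The main values here were log2 processed signals minus the 75th percentile of each array, so that a value of 0 is the 75th percentile of that array. The 2 samples hybridised on 2 arrays each were averaged over their arrays. Spots flagged by the scanner software as non-uniform or as population outliers were left out. A probe was tested when it was well above background in at least 3 of the 18 samples and had at least 2 values in every group. Missing values made up 0.116% of the matrix.

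Probes were named by matching their transcript accessions to a table of RefSeq symbols. Of 39429 probes, 26055 (66.1%) received a symbol and 13374 did not. The brightest probe stood for each gene, and transcripts without a symbol were kept under their accession. This left 20812 genes, of which 14007 had a symbol. Probe sequences and positions were not used here, so genomic coordinates are not given.

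Group means were fitted with limma 3.58.1 in R 4.3.3 as a model with 6 group means over all 18 samples, with 12 residual and 2.49 prior degrees of freedom. P-values came from limma's moderated, two-sided test and were adjusted by Benjamini and Hochberg over the 20812 genes of each comparison, with a threshold of 0.05. Errors beside log2 fold changes are standard errors of the fit, and intervals are 95% intervals. Errors beside group means are standard deviations over 3 samples. Where no array of the lower group was well above background, "at least" marks the fold against each array's lowest signal well above background. This bound is not strict. For arrays, the number of samples limits the precision. The design text names 3 mice each, and whether samples with one number come from one mouse is not given. If one mouse gave samples to several conditions, the p-values treat them as independent.

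The 25 gene lists were fixed before the data were examined, as were the comparisons, model, threshold and most alternative settings. The lists cover HIF hydroxylases and HIF subunits, hypoxia response, glycolysis, the ATF4 amino acid starvation response, the unfolded protein response, cholesterol biosynthesis, autophagy and lysosome, cell cycle, pro-apoptotic genes, anti-apoptotic genes, p53 targets, inflammatory cytokines, interferon-stimulated genes, alternative activation, antigen presentation, macrophage identity, oxidative phosphorylation and NRF2 targets. They also cover markers of neutrophils, lymphocytes, dendritic cells, osteoclasts, mast cells with basophils and eosinophils, erythroid cells with megakaryocytes, and stromal with endothelial cells. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, against all other genes. Some lists shared genes, such as Fas, so the 250 tests, adjusted together, were not independent. A correlation estimated per list, and limma's fry, were alternatives. Missing values were filled with their group mean for these tests alone.

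Named genes were chosen by a rule fixed with the lists. It takes Egln3 and the other HIF hydroxylases and subunits past the threshold. It takes the 8 largest rises and 8 largest falls of each comparison among genes past the threshold whose groups did not overlap (the same sign in all 3 conditions for the averaged genotype comparison), whose probe was well above background in all samples of at least 1 group and which had a gene symbol other than a predicted or clone name. It takes the 3 members with the smallest adjusted p of each list past its test, and always of the hypoxia, pro-apoptotic and anti-apoptotic lists. Members past the threshold of other lists could be named where there were at most 5.

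The alternative settings were quantile normalization, the authors' value table, no filter on dim probes, a filter on probes well above background in all 18 samples, the mean of a gene's probes, keeping flagged spots, 1 array of the samples hybridised more than once, slide as a block, the replicate number as a block, an intensity trend in the variance, only the groups compared, thresholds of 0.01 and of a 2-fold change, and leaving out each sample in turn. Background correction by normexp with an offset of 50 was meant for the mean spot signal, which the columns used here do not hold. It was run on the median signal instead, with the percentile scaling and with quantile normalization, a choice made after the data were seen. A fit without 3 samples that stood apart was also added then.

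The fit was tested on simulated data of the same size, with 200 changed genes in each of 5 runs. Values were drawn independently per gene and sample. The rates do not cover correlated genes, slide differences, samples that stand apart, shared mice or fewer changed genes. In 1 condition it recovered 29.3% of 1.5-fold, 71.9% of 2-fold and 88.5% of 4-fold genotype differences, with 4.97% false calls. Averaged over conditions it recovered 72.5%, 90.4% and 97.6%, with 5.45% false calls. Lyz2, near 2-fold, passed over all genes in no condition alone. In 10 runs without change 2 genes were called, and only a list shifted by 0.5 log2 units was called.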

Results

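The data comprised 18 samples of bone-marrow-derived macrophages in 6 groups of 3: wild-type and PHD3 knockout cells at oxygen 20, at oxygen 1, and at oxygen 20 after starvation. The series title names the survival of macrophages under stress as the subject. The comparisons therefore ask how low oxygen and starvation changed expression in each genotype, whether knockout cells differed from wild-type cells in any condition, and whether the responses differed between genotypes. A total of 20 arrays on 5 slides held 43020 spots each. Between 56.1% and 65.4% of spots per array were well above background, the 75th percentile of the processed signal lay between 933.8 and 1556, the median local background between 20 and 25, and no spot was saturated. The 2 arrays of a sample correlated at r = 0.990 for the knockout sample at oxygen 1 and r = 0.995 for the knockout control sample, across genes, which are not independent replicates. Other samples of these groups correlated at r = 0.993 and r = 0.990, so the arrays of the oxygen 1 sample agreed no better than different samples did. The authors' columns of these 2 samples correlated at 0.9999 and 1.0 with the first array, at 0.9895 and 0.9937 with the second, and at up to 0.9907 and 0.9941 with arrays of other samples.

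Egln3, the gene targeted in the knockout, was measured by 2 probes and its signal followed oxygen far more than genotype. On the log2 scale relative to the 75th percentile of the array, the first probe read -3.33 ± 0.33 (SD, n = 3) in wild-type controls, 3.04 ± 0.10 at oxygen 1 and -2.15 ± 0.10 in starved wild-type cells. The samples labelled knockout read -3.81 ± 0.21, 3.00 ± 0.12 and -2.27 ± 0.17 in the same conditions. The second probe read -3.93, 2.47 and -2.63 in wild type and -4.30, 2.41 and -2.81 in the knockout. Knockout minus wild type was -0.49 (95% interval -0.82 to -0.16) in controls, -0.038 (-0.37 to 0.29) at oxygen 1 and -0.12 (-0.45 to 0.21) when starved, with none past the limma threshold (adjusted p 1.00 in each). The difference in controls was -0.31 without replicate 1 of the wild-type controls and between -0.64 and -0.30 over all alternatives. Averaged over conditions it was -0.21 (-0.41 to -0.024), and -0.12 without the 3 samples that stood apart, which are replicate 1 of the wild-type controls, replicate 3 of the knockout controls and replicate 3 of the starved wild-type cells. Within slides the difference was -0.42 and -0.26 in controls, between -0.17 and 0.12 at oxygen 1 and -0.27 when starved. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the signal neither checks nor questions the genotype, and the samples are called knockout by their labels.

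In wild-type macrophages at oxygen 1, the genes that rose most were arginase 1 (Arg1), which converts arginine to ornithine and urea, at 357-fold, and Mgarp, a mitochondrial protein, at 356-fold. Ak4, a mitochondrial adenylate kinase, rose 74.7-fold, Egln3 82.3-fold and Gipr, the receptor of an incretin hormone, 211-fold. Smtnl2 rose 174-fold, while Ppp1r3g, a glycogen-targeting phosphatase subunit, rose at least 51.9-fold and Mboat2, a phospholipid acyltransferase, at least 13.8-fold. Of the control samples 1 of 3 was well above background for Arg1 and for Smtnl2, so the sizes of these folds rest on dim readings. The largest falls were of Cd209f, a C-type lectin, 23.4-fold, Ngp, a neutrophil granule protein, 13.7-fold, and Rab38, a small GTPase of lysosome-related organelles, 8.92-fold. Without replicate 2 at oxygen 1, the log2 changes of Cd209f and Ngp were -3.92 and -2.82 against -4.55 and -3.77. The chemokine Cxcl5 fell at least 11.4-fold, Omg at least 6.76-fold, the matrix protein Mgp at least 5.28-fold, the adhesion molecule Vcam1 at least 4.12-fold and the centromere protein Cenpm at least 2.54-fold. In all, 8037 of 20812 genes (38.6%) passed the limma threshold, 4314 rising and 3723 falling, and 2611 of them by at least 2-fold. The groups did not overlap for 10337 genes (49.7%), against the 10% that chance gives with 3 against 3.

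Genes of the hypoxia response rose together in wild-type cells. Of 42 measured, 36 rose and 1 fell, and the same counts held adjusted over the list alone (median log2 fold change 2.45, camera adjusted p = 5.60e-23). Fam162a rose 21.1-fold and the HIF target Ankrd37 47.1-fold. With the members below background set to their bounds the median was 2.30. The HIF hydroxylases and subunits gave 5 rises and 1 fall among 10 genes, also adjusted over the list alone (median 0.46, adjusted p = 0.0361; adjusted p = 0.247 with an estimated correlation). Egln1, which encodes PHD2, the main oxygen sensor of the HIF pathway, rose 5.25-fold, Vhl, part of the ubiquitin ligase that degrades HIF, 3.31-fold and Hif3a 1.61-fold, while Egln2 fell by 0.59 on the log2 scale. Epas1, the HIF-2 alpha subunit, rose by 0.32, a call lost with slide as a block (0.25, adjusted p = 0.186) and without replicate 2 of the wild-type controls (0.29, adjusted p = 0.0503), with adjusted p between 0.00941 and 0.186 over the alternatives. This list's call was lost without replicate 2 (adjusted p = 0.0551) or replicate 3 (0.0547) at oxygen 1, without replicate 1 of the controls (0.0558), and without the 3 samples that stood apart (0.0653).

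Glycolysis genes rose and cell-cycle genes fell in wild-type cells at oxygen 1. Of 20 glycolysis genes 19 rose and none fell, also adjusted over the list alone (median 1.99, adjusted p = 4.53e-17). The glucose transporter Slc2a1 rose 15.9-fold, from 2.32 ± 0.24 to 6.31 ± 0.16 (SD, n = 3, log2), the pyruvate dehydrogenase kinase Pdk1 8.92-fold and the triosephosphate isomerase Tpi1 4.80-fold. Of 47 cell-cycle genes 44 fell and none rose, or 45 adjusted over the list alone (median -1.63, adjusted p = 2.41e-27; adjusted p = 0.178 with an estimated correlation). The replication helicase subunit Mcm2 fell 4.23-fold, Uhrf1, which maintains DNA methylation, 4.93-fold and Gins2 3.01-fold. Of 25 cholesterol biosynthesis genes 11 fell and none rose, also adjusted over the list alone (median -0.51, adjusted p = 0.00735; adjusted p = 0.719 with an estimated correlation), among them Dhcr7 (2.22-fold), Fdps (2.15-fold) and Nsdhl (1.69-fold). That call was lost without replicate 2 at oxygen 1 (median -0.27, adjusted p = 0.0551). Of 51 oxidative phosphorylation genes 13 fell and 3 rose, also adjusted over the list alone (median -0.12, adjusted p = 0.0354; adjusted p = 0.614 with an estimated correlation). Ndufs1 of complex I fell 1.39-fold and Cox5a of cytochrome c oxidase 1.63-fold, while Ndufa4l2, a HIF target that restrains complex I, rose 3.05-fold. That call was lost with slide as a block (adjusted p = 0.164), with the filter on all 18 samples (0.0547), without the 3 samples that stood apart (0.0661), without replicate 3 at oxygen 1 (0.0646) and without replicate 1 (0.0605) or 3 (0.0634) of the controls, while quantile normalization moved the median to -0.26 and to -0.22 after normexp.

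The apoptosis lists moved in both directions at oxygen 1 in wild-type cells. Of 42 pro-apoptotic genes 11 rose and 10 fell, or 11 and 12 adjusted over the list alone (median 0.082, adjusted p = 0.562). Bnip3 and Bnip3l, mitochondrial proteins that drive the removal of mitochondria and can promote cell death, rose 22.4-fold and 5.66-fold, and Dapk2, a death-associated kinase, rose at least 20.1-fold. Bnip3 went from 2.39 ± 0.15 to 6.88 ± 0.24 (SD, n = 3, log2). Of 38 anti-apoptotic genes 15 rose and 6 fell, or 16 and 6 adjusted over the list alone (median 0.20, adjusted p = 0.310). Ier3, a stress-induced survival gene, rose 8.43-fold and the growth factor receptor Igf1r 2.79-fold, while Birc5 (survivin), which also acts in cell division, fell 3.29-fold. Neither list passed camera, and both passed fry (adjusted p = 8.23e-05 and 9.30e-07), which does not compare a list with other genes.

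Among the other lists none passed the test in wild-type cells at oxygen 1. Rises and falls numbered 10 and 17 for ATF4 targets (adjusted p = 0.221), 6 and 2 for the unfolded protein response (0.507), 13 and 4 for autophagy and lysosome (0.437), 6 and 14 for p53 targets (0.0858), 18 and 12 for inflammatory cytokines (0.130) and 11 and 2 for interferon-stimulated genes (0.158). They numbered 7 and 6 for alternative activation (0.976), 8 and 3 for antigen presentation (0.310), 9 and 7 for macrophage identity (0.759) and 10 and 8 for NRF2 targets (0.980). Markers of other cell types gave 5 and 7 for neutrophils (0.442), 3 and 5 for lymphocytes (0.861), 4 and 3 for dendritic cells (0.788), 4 and 3 for osteoclasts (0.959), 3 and 3 for erythroid cells and megakaryocytes (0.730) and 4 and 6 for stromal and endothelial cells (0.313). They numbered 2 and 2 for mast cell, basophil and eosinophil markers (0.964), where the eosinophil receptors Ccr3 and Siglecf rose 7.51-fold and 3.49-fold, the cytokine Il4 fell 3.14-fold and the receptor Kit changed by -1.12 on the log2 scale (adjusted p = 0.0246). The call of Kit was lost under 7 of 13 alternatives, among them leaving out replicate 1 (0.0620) or 3 (0.0725) at oxygen 1 and replicate 2 (0.0845) or 3 (0.1065) of the controls. Its log2 change was -0.17 within the slide that held both groups. In 6 of the 19 lists that did not pass the median, the mean and the test differed in sign, among them alternative activation, with a median of -0.13 and a mean of 0.42.

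In knockout macrophages at oxygen 1 the largest rises were again of Mgarp (702-fold), Gipr (324-fold), Smtnl2 (170-fold), Egln3 (112-fold) and Ak4 (96.2-fold). Arg1 rose at least 215-fold and Ppp1r3g at least 48.6-fold, and F13a1, the catalytic subunit of coagulation factor XIII, rose 68.0-fold. For Mgarp and Gipr 1 of 3 controls was well above background, and for Mgp 1 of 3 samples at oxygen 1. Cd209f fell 29.5-fold, Rab38 9.92-fold, Emid1 9.44-fold, Cxcl5 8.76-fold and Mgp 8.42-fold, and Ngp fell at least 9.94-fold, Omg at least 8.06-fold and Vcam1 at least 3.58-fold. A total of 8290 genes (39.8%) passed the limma threshold, 4654 rising and 3636 falling, and 2762 of them by at least 2-fold. The groups did not overlap for 10205 genes (49.0%), against the 10% that chance gives.

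The knockout cells showed the gene groups of low oxygen in these directions. Of 42 hypoxia response genes 34 rose and 2 fell, or 35 and 2 adjusted over the list alone (median 2.25, adjusted p = 2.66e-21), with Fam162a at 22.7-fold and Ankrd37 at 65.9-fold. Of 20 glycolysis genes 18 rose and none fell, also adjusted over the list alone (median 1.97, adjusted p = 2.08e-15), with Slc2a1 at 17.5-fold, Pdk1 at 10.3-fold and the lactate exporter Slc16a3 at 21.5-fold. Of 47 cell-cycle genes 44 fell and none rose, or 44 and 1 adjusted over the list alone (median -1.60, adjusted p = 5.40e-26; adjusted p = 0.178 with an estimated correlation), with Mcm2 falling 4.78-fold, Uhrf1 5.01-fold and Gins2 3.63-fold. Of 25 cholesterol genes 14 fell and none rose, or 14 and 1 adjusted over the list alone (median -0.65, adjusted p = 7.35e-04; adjusted p = 0.614 with an estimated correlation), with Dhcr7 falling 2.54-fold and Fdps 2.31-fold. Oxidative phosphorylation gave 12 falls and 3 rises among 51 genes, also adjusted over the list alone (median -0.12, adjusted p = 0.0354; adjusted p = 0.614 with an estimated correlation), with Uqcrc2 of complex III falling 1.31-fold. That call was lost with slide as a block (0.1004), with the filter on all 18 samples (0.0557), without the 3 samples that stood apart (0.138), without replicate 3 at oxygen 1 (0.108) and without replicate 3 of the controls (0.128), and quantile normalization moved the median to -0.28 and to -0.30 after normexp. The HIF hydroxylases and subunits gave 5 rises and 1 fall, also adjusted over the list alone, and did not pass the list test (median 0.40, adjusted p = 0.0583). Egln1 rose 4.92-fold, Vhl 3.75-fold and Hif3a 1.46-fold (0.0178, lost without replicate 3 at oxygen 1, 0.0670, or without replicate 1, 0.0580, or 2, 0.0868, of the controls), while Egln2 fell by 0.69 on the log2 scale. Epas1 rose 1.19-fold in a call that 10 alternatives ended (adjusted p between 0.0118 and 0.264), among them leaving out replicate 2 of the controls (0.14) and any of the replicates at oxygen 1 (0.24, 0.25 and 0.24).

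The pro-apoptotic list gave 12 rises and 10 falls in knockout cells at oxygen 1, or 14 and 12 adjusted over the list alone (median 0.14, adjusted p = 0.538). Bnip3 rose 25.2-fold, Bnip3l 6.10-fold and Dapk2 at least 21.4-fold. The anti-apoptotic list gave 15 rises and 5 falls, or 16 and 7 adjusted over the list alone (median 0.15, adjusted p = 0.313). Ier3 rose 8.98-fold and Igf1r 3.18-fold, and Birc5 fell 3.22-fold. Both lists passed with fry alone (adjusted p = 2.25e-05 and 2.98e-07). Over the 20 lists that did not pass in knockout cells, medians lay between -0.26 and 0.55 and adjusted p between 0.0583 and 0.987, and in 5 of them the median, mean and test differed in sign.

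Control and oxygen 1 samples shared 1 slide in wild type and 3 slides in the knockout. The within-slide median of the hypoxia response was 2.46 in wild type and between 2.27 and 2.48 in the knockout, against 2.35 and 2.19 with slide as a block. It was 2.05 and between 1.85 and 1.99 for glycolysis (2.03 and 1.99 with the block), -1.69 and between -1.83 and -1.27 for the cell cycle (-1.71 and -1.56), and -0.92 and between -0.69 and -0.28 for cholesterol (-0.53 and -0.58). It was 0.52 for the HIF hydroxylases in wild type (0.55 with the block), and -0.18 and between -0.16 and -0.067 for oxidative phosphorylation (-0.12 and -0.084). Slc2a1 rose by 3.83 on the log2 scale within the slide in wild type and by 4.13 to 4.25 in the knockout, Bnip3 by 4.39 and by 4.46 to 5.24, and Mcm2 changed by -2.12 and by -2.50 to -1.84. With slide as a block 8136 and 8619 genes passed in wild type and knockout, 7083 and 7749 of them also in the fit without it. Over all comparisons, 62 of 250 list tests passed. With an estimated correlation 4 held, those of the hypoxia response (adjusted p = 6.86e-04 in both genotypes) and of glycolysis (0.0433 in wild type and 0.0495 in the knockout) at low oxygen, and with fry 5 of 6 and 5 of 5 at low oxygen and 7 of 8 and 8 of 9 under starvation did, in wild type and knockout. Fry also called 8 and 9 lists at low oxygen and 5 and 4 under starvation that did not pass camera. The normexp correction on the median signal called 3909 and 4221 genes. It ended the calls of Vcam1, Mgp, Ndufa4l2, Il4 and Epas1 in both genotypes and of Cenpm and Kit in wild type, with adjusted p between 0.0666 and 0.825 in wild type and between 0.0981 and 0.322 in the knockout. The log2 changes of the genes it removed were between 15.7% and 106% and between 18.9% and 94.0% of those above. It also moved the folds of 18 of 45 and 17 of 44 named genes by over 1.5 times, with log2 changes of 5.63 against 8.48 for Arg1, 6.57 against 8.48 for Mgarp, 5.51 against 7.72 for Gipr, 5.06 against 7.44 for Smtnl2 and 5.64 against 6.36 for Egln3 in wild type. In the knockout they were 7.02 against 9.46 for Mgarp, 5.79 against 8.34 for Gipr, 4.40 against 6.09 for F13a1, -1.35 against -3.24 for Emid1 and -1.30 against -3.13 for Cxcl5.

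**Figure D1:**
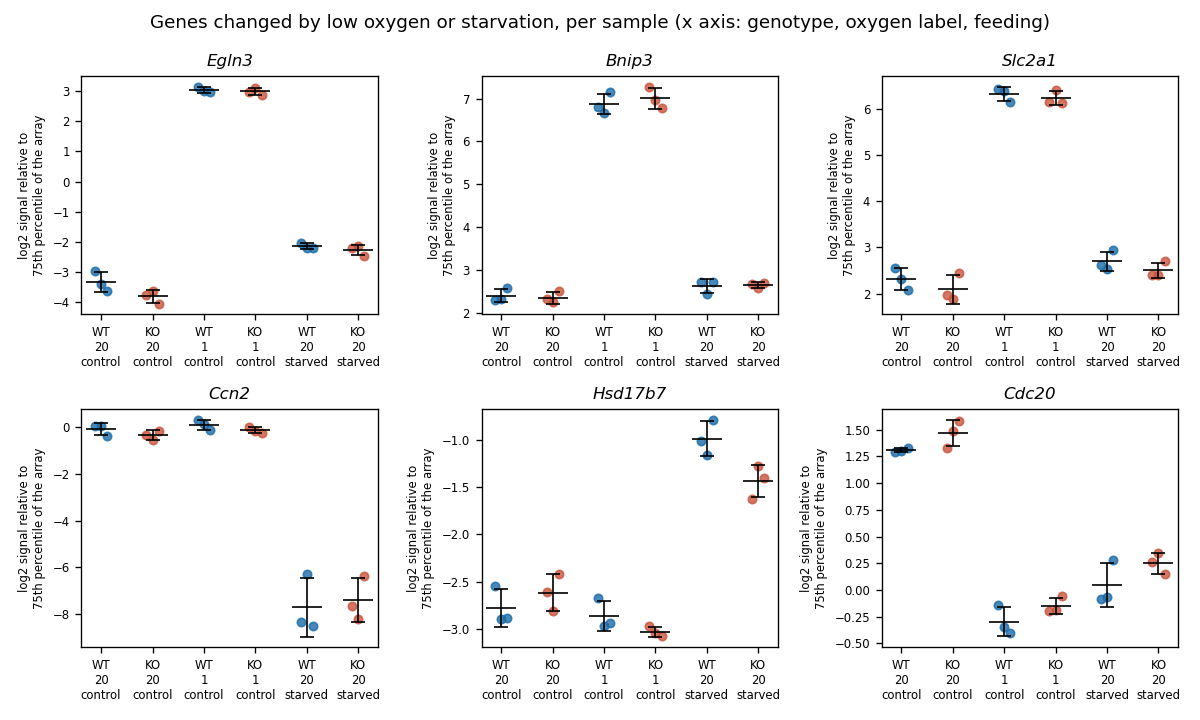
Log2 signal relative to the 75th percentile of the array (y axis) of 6 genes in each of the 18 samples, by genotype, oxygen label and feeding (x axis), with wild type in blue and knockout in red; points are samples and bars give the mean ± SD of 3 samples. Slc2a1 rose 15.9-fold and 17.5-fold at oxygen 1 in wild type and knockout, and Hsd17b7 rose 3.44-fold and 2.26-fold in starved cells, while the values of Ccn2 in starved cells were not well above background.

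In starved wild-type macrophages the largest falls included Ccn2, Myl9, Actg2 and Ngp. Ccn2, a matricellular growth factor induced by serum, fell at least 72.3-fold, from -0.086 ± 0.25 (SD, n = 3, log2) to a signal not well above background in any of the 3 starved samples. Myl9, a myosin light chain, fell 24.7-fold, the smooth muscle actin Actg2 at least 15.0-fold, calponin (Cnn1) at least 9.10-fold, the collagen receptor subunit Itga11 at least 9.16-fold and the protease inhibitor Timp3 at least 7.25-fold. The neutrophil granule gene Ltf fell 23.7-fold, with 1 of 3 starved samples well above background, and Ngp at least 14.9-fold. The largest rises were of Cdkn1c, an inhibitor of cyclin-dependent kinases, 12.98-fold, Tspan7, a tetraspanin, 11.3-fold, the fatty acid desaturase Scd1 10.73-fold and Atp13a4, well above background in 1 of 3 controls, 10.6-fold. The engulfment receptor Megf10 rose at least 4.96-fold, the desaturase Fads2 at least 3.88-fold and the cytochrome Cyp2s1 at least 3.83-fold. Plxna4 also passed the threshold, from a signal not well above background in the controls, and no fold is given for it. In all, 2596 genes (12.5%) passed the limma threshold, 1433 rising and 1163 falling, and 851 of them by at least 2-fold. The groups did not overlap for 6114 genes (29.4%), against the 10% that chance gives. Without replicate 1 of the starved samples 1664 genes passed.

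Cholesterol biosynthesis rose and the cell cycle fell in starved wild-type cells. Of 25 cholesterol genes 23 rose and none fell, or 24 adjusted over the list alone (median 1.24, adjusted p = 3.15e-23; adjusted p = 0.155 with an estimated correlation). Hsd17b7 rose 3.44-fold, from -2.77 ± 0.20 to -0.99 ± 0.19 (SD, n = 3, log2), Acat2 2.79-fold and Nsdhl 2.36-fold, all enzymes of the pathway. Of 47 cell-cycle genes 40 fell and 1 rose, or 44 and 1 adjusted over the list alone (median -1.001, adjusted p = 2.86e-32; adjusted p = 0.155 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, fell 2.40-fold, Ube2c 2.64-fold and the condensin subunit Ncapd2 1.87-fold. Of 38 ATF4 targets 13 fell and 1 rose, or 16 and 1 adjusted over the list alone (median -0.35, adjusted p = 5.85e-08; adjusted p = 0.362 with an estimated correlation). Nupr1, a stress-induced nuclear protein, fell 1.92-fold, the serine hydroxymethyltransferase Shmt2 1.61-fold and the amino acid transporter Slc7a5 2.03-fold. Of 20 glycolysis genes 7 rose and none fell, or 10 and 1 adjusted over the list alone (median 0.35, adjusted p = 3.62e-04; adjusted p = 0.362 with an estimated correlation), with Aldoc at 3.06-fold, Eno2 at 2.05-fold and Pkm at 1.38-fold.

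Of 39 interferon-stimulated genes 6 fell and none rose in starved wild-type cells, also adjusted over the list alone (median -0.21, adjusted p = 6.23e-04; adjusted p = 0.652 with an estimated correlation). The chemokine Cxcl10 fell 2.84-fold, interferon beta (Ifnb1) 2.79-fold and the GTPase Gbp5 2.18-fold. Without replicate 3 of the controls the interferon median was -0.12. Of 30 p53 targets 11 rose and 3 fell, or 13 and 3 adjusted over the list alone (median 0.22, adjusted p = 0.0361; adjusted p = 0.468 with an estimated correlation). The cell-cycle inhibitor Cdkn1a rose 1.83-fold and the p53 antagonist Mdm2 1.49-fold, while the death receptor Fas fell 1.65-fold. The p53 call was lost without replicate 3 of the controls (0.0658), without replicate 3 of the starved samples (0.199), without the 3 samples that stood apart (0.230) and with the filter on all 18 samples (0.0607).

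Of 20 neutrophil markers 7 fell and 2 rose in starved wild-type cells, also adjusted over the list alone (median -0.41, adjusted p = 0.00695; adjusted p = 0.511 with an estimated correlation). Camp fell 3.40-fold and Stfa2l1 rose 3.99-fold. With the filter on all 18 samples the median was -0.072 (adjusted p = 0.455), and without replicate 3 of the controls it was -0.26. Of 20 stromal and endothelial markers 9 fell and 1 rose, or 9 and 2 adjusted over the list alone (median -0.50, adjusted p = 6.14e-07; adjusted p = 0.155 with an estimated correlation), with the matrix proteins Postn and Sparc falling 7.24-fold and 6.59-fold. With normexp and quantile normalization the stromal median was -0.33. The hypoxia response gave 8 rises and 2 falls, also adjusted over the list alone, and did not pass (median 0.16, adjusted p = 0.0729). It passed under 6 of 15 alternatives, which were quantile normalization (0.0379), also after normexp (median 0.088, 0.0487), no filter on dim probes (0.0339), the filter on all 18 samples (0.0258), leaving out replicate 2 of the starved samples (0.0269) and fry (0.00149), with adjusted p between 0.00149 and 0.459 over all of them. Its members included the chemokine receptor Cxcr4, which rose 4.62-fold, the repressor Bhlhe40, 3.13-fold, and Ankrd37, 1.89-fold. Of the HIF hydroxylases and subunits (adjusted p = 0.603), Egln3 rose 2.26-fold, Hif3a fell by 0.78 and Egln2 by 0.41 on the log2 scale, the last in a call that was lost without any of 5 single samples.

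The apoptosis lists did not pass camera in starved wild-type cells. Pro-apoptotic genes gave 6 rises and 4 falls, also adjusted over the list alone (median 0.075, adjusted p = 0.697), with Bnip3l rising 1.57-fold and Bok, a BCL2 family member, falling at least 4.17-fold. Anti-apoptotic genes gave 3 rises and 7 falls, or 4 and 8 adjusted over the list alone (median -0.048, adjusted p = 0.164). The BCL2 homologues Bcl2a1d and Bcl2a1c fell 2.12-fold and 2.19-fold and Birc5 2.67-fold. The anti-apoptotic list passed with fry alone (adjusted p = 8.37e-04), and its median was 0.021 without replicate 3 of the controls. Among the remaining lists, rises and falls numbered 1 and 3 for the unfolded protein response (adjusted p = 0.499), 6 and 0 for autophagy and lysosome (0.0549), 8 and 9 for inflammatory cytokines (0.300), 4 and 4 for alternative activation (0.670), 4 and 1 for antigen presentation (0.788), 9 and 2 for macrophage identity (0.130), 1 and 1 for oxidative phosphorylation (0.892) and 5 and 2 for NRF2 targets (0.639). They numbered 4 and 2 for lymphocytes (0.577), 1 and 1 for dendritic cells (0.903), 5 and 1 for osteoclasts (0.0549), 0 and 1 for mast cells, basophils and eosinophils (0.662) and 5 and 2 for erythroid cells and megakaryocytes (0.277). In 3 of the 17 lists that did not pass the median, mean and test differed in sign, among them inflammatory cytokines, with a median of -0.21 and a mean of 0.10.

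In starved knockout macrophages Ccn2 fell at least 66.9-fold, Myl9 38.2-fold, Actg2 at least 12.8-fold, Cnn1 at least 8.01-fold and Timp3 at least 6.97-fold, with Lurap1l falling at least 2.92-fold. Ltf fell 17.4-fold, with 2 of 3 starved samples well above background, and Ngp at least 12.4-fold. Cdkn1c rose 16.4-fold, the matrix protease Mmp3 14.9-fold, Tspan7 12.6-fold and Inhba, a subunit of activin, 11.2-fold. Megf10 rose at least 4.47-fold, Angptl2 at least 4.10-fold, the glutathione transferase Gsta2 at least 3.48-fold and Cyp2s1 at least 3.17-fold. A total of 2791 genes (13.4%) passed the limma threshold, 1504 rising and 1287 falling, and 868 of them by at least 2-fold. The groups did not overlap for 6411 genes (30.8%), against the 10% that chance gives.

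Cholesterol biosynthesis gave 22 rises and no falls in starved knockout cells, or 25 and 0 adjusted over the list alone (median 0.97, adjusted p = 1.96e-17; adjusted p = 0.187 with an estimated correlation), with Hsd17b7 rising 2.26-fold and Msmo1 2.25-fold. The cell cycle gave 38 falls and 1 rise, or 43 and 1 adjusted over the list alone (median -0.95, adjusted p = 1.25e-29; adjusted p = 0.155 with an estimated correlation), with Cdc20 falling 2.33-fold and Nusap1 2.29-fold. ATF4 targets gave 10 falls and 2 rises, or 15 and 2 adjusted over the list alone (median -0.27, adjusted p = 7.89e-05; adjusted p = 0.463 with an estimated correlation). Nupr1 fell 2.24-fold and Ddit4, an inhibitor of mTOR signalling, rose 1.83-fold. The ATF4 median was -0.13 without replicate 3 of the starved samples and -0.17 with normexp and quantile normalization. Glycolysis gave 3 rises and no falls, also adjusted over the list alone (median 0.26, adjusted p = 0.00560; adjusted p = 0.463 with an estimated correlation), with Aldoc at 2.49-fold. The hypoxia response gave 11 rises and 1 fall, or 12 and 1 adjusted over the list alone (median 0.18, or 0.13 with members below background at their bounds; adjusted p = 7.90e-04; adjusted p = 0.187 with an estimated correlation), with Cxcr4 rising 5.48-fold and Ankrd37 2.37-fold. Egln3 rose 2.91-fold, Hif3a fell by 0.90 on the log2 scale and Egln2 by 0.46, the last in a call that was lost without any of 3 single samples (adjusted p 0.0705, 0.0560 and 0.0600).

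The p53 targets gave 11 rises and 2 falls in starved knockout cells, or 12 and 2 adjusted over the list alone (median 0.15, adjusted p = 0.00368; adjusted p = 0.362 with an estimated correlation), with Phlda3 rising 1.88-fold and Mdm2 1.73-fold. The p53 median was 0.33 without replicate 3 of the controls, and 0.23 and 0.24 without replicate 1 or 2 of the starved samples. NRF2 targets gave 9 rises and 2 falls, or 10 and 2 adjusted over the list alone (median 0.12, adjusted p = 0.0354; adjusted p = 0.765 with an estimated correlation), with the detoxifying enzymes Ephx1 and Gsta1 rising 2.96-fold and at least 2.88-fold. That call was lost without replicate 1 (0.0862) or 2 (0.153) of the controls, without replicate 1 of the starved samples (median 0.068, 0.318) and with the filter on all 18 samples (0.192), and the median was 0.20 without replicate 3 of the controls and 0.22 without replicate 2 of the starved samples. Neutrophil markers gave 6 falls and 2 rises, or 7 and 2 adjusted over the list alone (median -0.59, adjusted p = 0.0177; adjusted p = 0.597 with an estimated correlation), with Camp falling 3.69-fold. That call was lost without replicate 2 of the controls (median -0.29, adjusted p = 0.0899) and with the filter on all 18 samples (0.474), and the median was -0.23 with normexp and quantile normalization. Stromal and endothelial markers gave 8 falls and 1 rise, or 9 and 1 adjusted over the list alone (median -0.52, adjusted p = 2.35e-05; adjusted p = 0.187 with an estimated correlation), with Col1a1, a chain of type I collagen, falling 11.5-fold and Postn 9.08-fold. The stromal median was -0.23 with normexp and quantile normalization.

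Pro-apoptotic genes gave 6 rises and 2 falls in starved knockout cells, also adjusted over the list alone (median 0.022, adjusted p = 0.507), with Bcl2l11 (BIM), an activator of mitochondrial apoptosis, rising 2.65-fold and Fas falling 1.84-fold. Anti-apoptotic genes gave 2 rises and 9 falls, or 5 and 10 adjusted over the list alone (median -4.1e-04, adjusted p = 0.197), with Bcl2a1d falling 2.33-fold and the kinase Sgk1 rising 1.81-fold. The anti-apoptotic list passed with fry alone (adjusted p = 3.58e-04). The interferon list did not pass (1 rise, 3 falls, median 0.051, adjusted p = 0.922). Autophagy and lysosome gave 5 rises and no falls, or 4 and 0 adjusted over the list alone (adjusted p = 0.0666), among them the proton pump subunit Atp6v0d2 at 4.60-fold, Gpnmb at 2.85-fold and the protease Ctsl at 1.81-fold. Over the 16 lists that did not pass in the knockout, adjusted p lay between 0.0666 and 0.9983, and in 8 of them the median, mean and test differed in sign.

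Control and starved samples shared 3 slides in each genotype. Within slides the median of the cholesterol list was between 1.10 and 1.35 in wild type and between 0.79 and 1.32 in the knockout (1.24 and 0.99 with slide as a block), and that of the cell cycle between -1.06 and -0.92 and between -1.01 and -0.95 (-1.001 and -0.96). The stromal list lay between -0.80 and -0.50 and between -0.73 and -0.12 (-0.50 and -0.48), neutrophil markers between -0.76 and -0.22 and between -0.70 and -0.37 (-0.41 and -0.61), and ATF4 targets between -0.35 and -0.29 and between -0.36 and -0.053 (-0.35 and -0.27). Glycolysis lay between 0.24 and 0.33 and between 0.13 and 0.36 (0.36 and 0.27), and p53 targets between 0.17 and 0.37 and between 0.18 and 0.39 (0.22 and 0.16). The interferon list in wild type lay between -0.21 and -0.13 (-0.21), and the hypoxia and NRF2 lists in the knockout between 0.11 and 0.39 (0.18) and between -0.0068 and 0.28 (0.12). Within slides Hsd17b7 changed by 1.53 to 2.09 in wild type and by 1.01 to 1.53 in the knockout, and Cdc20 by -1.38 to -1.05 and by -1.43 to -1.09. With slide as a block 2586 and 2827 genes passed, 2334 and 2523 of them also without it. The normexp correction called 1128 and 898 genes. It ended the calls of 26 of 64 named genes in wild type and 29 of 77 in the knockout, among them Ngp, Cnn1, Timp3, Ifnb1, Gbp5 and Egln2 in both, Actg2, Itga11, Ltf, Bok, Bnip3l, Mdm2, Pkm, Slc7a5 and Hif3a in wild type, and Megf10, Cyp2s1, Angptl2, Gsta1, Gsta2 and Lurap1l in the knockout (adjusted p between 0.0513 and 0.977 and between 0.0557 and 1.00). The log2 changes of these genes were between -26.6% and 121% and between 18.2% and 104% of those above, with Egln2 at -0.48 against -0.41 and Bok at -0.021 against -2.60 in wild type. Among the calls it left, log2 changes were 1.95 against 3.42 for Scd1, 1.92 against 3.41 for Atp13a4 and -2.84 against -4.63 for Myl9 in wild type, and 2.14 against 3.90 for Mmp3 and -3.37 against -5.26 for Myl9 in the knockout. That correction shifted the median of all genes in starved wild-type cells by 0.16, and the medians of knockout minus wild type when starved and of the starvation interaction by -0.13 and -0.14.

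Both genotypes responded alike at the level of the whole profile. Across the 20812 genes, which are not independent replicates, the low-oxygen changes of wild type and knockout correlated at r = 0.926 (Spearman 0.884), with 3760 genes rising and 3068 falling in both and 1 moving in opposite directions. Independent lists would share 964.7 and 650.4, with 1586 opposite. The starvation changes correlated at r = 0.815 (Spearman 0.740), with 1129 rising and 924 falling in both and 0 opposite, against 103.6, 71.9 and 172.7. Low oxygen and starvation overlapped less within a genotype. In wild type r was 0.374, with 743 genes rising and 676 falling under both and 302 moving in opposite directions, against 297, 208 and 497 for independent lists. In the knockout r was 0.417, with 879, 750 and 287 genes, against 336, 225 and 551. Both responses were measured against the same control samples. In 100 simulations without any change, the shared controls alone gave a mean r of 0.501. Groups of equal size give this by construction, so it is no measure for the r above. The simulated covariance was 0.0386, against 0.146 in wild type and 0.169 in the knockout, which left 0.108 and 0.131. The 3 controls per genotype were not split, since 1 part would have held a single sample, and part of the excess over independent lists may come from the shared controls.

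Lyz2, which encodes the lysozyme of macrophages and neutrophils, was lower in knockout than in wild-type macrophages in all conditions. It read 5.55 ± 0.087 against 6.55 ± 0.21 in controls, 4.57 ± 0.33 against 5.57 ± 0.14 at oxygen 1 and 5.50 ± 0.21 against 6.57 ± 0.17 when starved (SD, n = 3, log2), and every knockout sample lay below every wild-type sample of its condition. The difference averaged over conditions was -1.02 ± 0.095 (95% interval -1.23 to -0.82), or 2.03-fold, with a limma adjusted p of 5.14e-04. Over the alternatives it lay between -1.09 and -0.97, with adjusted p between 1.3e-04 and 0.00749. Within slides it was -1.01 and -0.80 in controls, between -1.21 and -0.68 at oxygen 1 and -1.14 when starved. Hhipl1, a protein of the hedgehog-interacting family, was lower by an averaged 2.14-fold (-1.10 ± 0.12, interval -1.36 to -0.84, adjusted p = 0.00248), and Cyp4a10, a fatty acid hydroxylase, by 1.64-fold (-0.71 ± 0.11, interval -0.95 to -0.48, adjusted p = 0.0451). The call of Cyp4a10 was lost in 16 of the 18 fits that left out 1 sample and under 4 other alternatives, with adjusted p between 0.00775 and 0.920.

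Averaged over the 3 conditions, 5 genes differed between genotypes, 1 higher and 4 lower in the knockout. The other two were transcripts without a symbol, named here after their values were seen, NM_146065 at -0.92 ± 0.12 (adjusted p = 0.0113) and XM_001476382, the 1 called higher (adjusted p = 0.00855). The first lost its call in the authors' value table (0.173), with the mean of a gene's probes (-0.45, 0.275), with the first array alone (0.152) and at stricter thresholds. The second was well above background in 0, 1 and 0 of 3 wild-type samples and in 1, 3 and 3 of 3 knockout samples in controls, at oxygen 1 and when starved, so no size is given. Its call was lost under 7 of 34 alternatives, which were slide as a block (0.198), the first (0.0597) or second (0.0705) array alone, an intensity trend (0.0586), a 2-fold threshold and both normexp settings, of which the one with percentile scaling turned its direction (0.956). At an unadjusted p below 0.05 there were 518 genes, where 1040.6 would be expected by chance. In each condition alone limma called 0 genes, and 284 genes in controls, 365 at oxygen 1 and 393 when starved had an unadjusted p below 0.05. In controls the groups did not overlap for 1036 genes (4.98%), below the 10% that chance gives. Slide as a block left 3 genes in the averaged comparison and 0 in each condition. The interaction of genotype with low oxygen and with starvation gave 0 genes each by limma, with 243 and 213 at an unadjusted p below 0.05.

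Erythropoietin (Epo), the hormone that drives red cell formation and a HIF target, read lower in knockout than in wild-type cells at oxygen 1, without passing over all genes. It was well above background in 1 of 3 knockout and 3 of 3 wild-type samples, and in none of the other 12 samples, so no size is given. The difference did not pass over all genes (limma adjusted p = 0.409), while it passed adjusted over the list alone. It passed over all genes without replicate 3 of the knockout samples at oxygen 1 (adjusted p = 0.0323) and had adjusted p between 0.0323 and 1.00 over the alternatives. Angptl4, a secreted inhibitor of lipoprotein lipase on the same list, was higher in the knockout by 0.61 ± 0.12 when starved (limma adjusted p = 0.388) and by 0.35 ± 0.068 averaged (0.296), which passed adjusted over the list alone and not over all genes. Within the slide that held both starved groups it was 0.73. The averaged difference passed over all genes without replicate 2 of the starved knockout samples (0.40, adjusted p = 0.0426), and adjusted p lay between 0.117 and 1.00 and between 0.0426 and 0.920 over the alternatives.

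**Figure D2:**
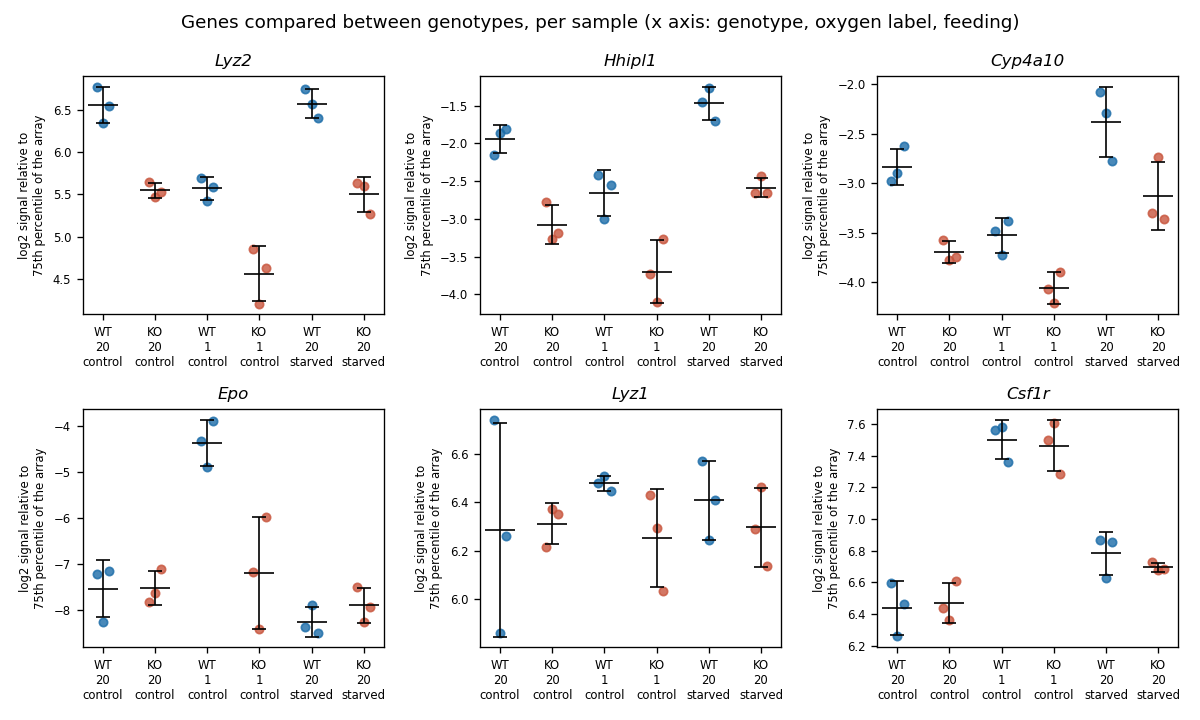
Log2 signal relative to the 75th percentile of the array (y axis) of 6 genes in each of the 18 samples, by genotype, oxygen label and feeding (x axis), with wild type in blue and knockout in red; points are samples and bars give the mean ± SD of 3 samples. Lyz2 was lower in every knockout sample than in every wild-type sample of its condition (averaged difference -1.02), whereas the related gene Lyz1 differed by -0.10 (95% interval -0.32 to 0.11). The values of Epo outside oxygen 1 were not well above background, and at oxygen 1 those of 1 of 3 knockout samples were.

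The apoptosis lists did not pass camera between genotypes. Knockout minus wild type, the median of the 42 pro-apoptotic genes was -0.024 in controls, 0.0049 at oxygen 1, 0.0049 when starved and -0.0015 averaged (camera adjusted p = 0.247, 0.939, 0.976 and 0.538). That of the 38 anti-apoptotic genes was -0.037, -0.012, -0.032 and -0.023 (adjusted p = 0.267, 0.445, 0.267 and 0.0750). The averaged anti-apoptotic list passed under 3 of 27 alternatives, with medians of -0.045 with normexp and quantile normalization (0.0199), -0.031 without replicate 2 of the knockout controls (0.0388) and -0.025 without replicate 1 of the starved knockout samples (0.0377). Its median lay between -0.045 and -0.010 and its adjusted p between 0.0199 and 0.271 over all alternatives. No member passed over all genes or adjusted over the list alone. The hypoxia response had a median of -0.059 in controls (adjusted p = 4.16e-04; adjusted p = 0.178 with an estimated correlation; 0.0730 with slide as a block), 0.031 at oxygen 1 and 0.0053 when starved (0.281). When starved it passed with slide as a block (0.010, 0.0160) and with normexp and quantile normalization (0.050, 0.00589).

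Small shifts of several lists passed the list test between genotypes, with no member but Lyz2 past the threshold over all genes. Each of their 29 medians moved by over 1.5 times under at least 1 alternative, 27 of them when a single sample was left out. Cell-cycle genes were higher in the knockout by a median of 0.13 in controls (adjusted p = 1.11e-07; adjusted p = 0.482 with an estimated correlation), 0.18 at oxygen 1 (1.20e-07; adjusted p = 0.483 with an estimated correlation) and 0.15 when starved (6.95e-08; adjusted p = 0.476 with an estimated correlation). Averaged over conditions the median was 0.17, with 47 of 47 genes positive (adjusted p = 2.62e-18; adjusted p = 0.256 with an estimated correlation) and Plk1, a mitotic kinase, at 0.27 ± 0.09. Within slides it ranged from -0.020 to 0.085 in controls and from -0.13 to 0.53 at oxygen 1, and it was 0.076 when starved. With slide as a block it was 0.048 in controls, no longer past the threshold (0.0636), 0.18 at oxygen 1, 0.061 when starved and 0.097 averaged. Without replicate 3 of the knockout samples at oxygen 1 the median there was 0.0094 (0.844) and the averaged one 0.10. It was 0.27 at oxygen 1 without replicate 1 of the wild-type samples, and 0.076 when starved without replicate 2 of the starved knockout samples.

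Cholesterol genes were lower in starved knockout cells, with a median of -0.25 (adjusted p = 1.18e-09; adjusted p = 0.362 with an estimated correlation), -0.32 within the 1 slide that held both groups and -0.32 with slide as a block, with Hsd17b7 at -0.45 ± 0.14. The median was -0.12 and -0.39 without replicate 1 or 2 of the starved knockout samples. At oxygen 1 the median was -0.080 (adjusted p = 0.0136; adjusted p = 0.756 with an estimated correlation). It was between -0.26 and 0.29 within slides and -0.044 with the block (0.0573), turned to 0.0088 and 0.0052 without replicate 1 or 3 of the wild-type samples at oxygen 1, and was -0.14, -0.047 and -0.056 without replicate 1, 2 or 3 of the knockout samples there and -0.23 without replicate 2 of the wild-type samples. Averaged over conditions it was -0.11 (adjusted p = 1.22e-05; adjusted p = 0.483 with an estimated correlation), or -0.12 with slide as a block, and it was -0.050 and -0.071 without replicate 1 or 3 of the wild-type samples at oxygen 1 and -0.16 without replicate 2 of the starved knockout samples. Interferon-stimulated genes were lower in knockout controls (median -0.14, adjusted p = 2.69e-09; adjusted p = 0.394 with an estimated correlation), between -0.37 and -0.17 within slides and -0.15 with slide as a block, but -0.065 without replicate 3 of the wild-type controls. When starved their median was 0.083 (adjusted p = 0.00338; adjusted p = 0.719 with an estimated correlation), -0.11 within the slide that held both groups and 0.081 with the block. It turned to -0.028 without replicate 1 of the starved knockout samples and fell to 0.0092 without replicate 1 of the starved wild-type samples, and was 0.14 without replicate 3 of either starved group. Neutrophil markers were lower in knockout controls (median -0.30, adjusted p = 7.11e-04; adjusted p = 0.400 with an estimated correlation), -0.79 and 0.055 within slides and -0.33 with the block. That call was lost without replicate 3 of the knockout controls (-0.075, adjusted p = 0.582), without replicate 1 of the wild-type controls (-0.20, 0.0758) and without the 3 samples that stood apart, which turned the median to 0.058, and the median was -0.45 without replicate 2 of the knockout controls. Their averaged median was -0.20 (adjusted p = 2.56e-05; adjusted p = 0.353 with an estimated correlation), or -0.21 with the block, and it was -0.10 (0.0747) without the 3 samples that stood apart. Macrophage identity genes had an averaged median of -0.037 (adjusted p = 3.36e-04; adjusted p = 0.222 with an estimated correlation), or -0.046 with the block, and lay between -0.064 and -0.056 without replicate 2 of the knockout samples at oxygen 1, replicate 1 of the starved knockout samples or replicate 3 of the starved wild-type samples, and at -0.065 without replicate 2 of the wild-type controls.

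In total 29 list tests between genotypes passed, and none of them held with an estimated correlation, where adjusted p lay between 0.178 and 0.756, or with fry. In controls these also included ATF4 targets (median -0.046; adjusted p = 0.719 with an estimated correlation), p53 targets (-0.061; 0.438), inflammatory cytokines (-0.057; 0.463), NRF2 targets (-0.094; 0.633) and stromal markers (-0.12; 0.377). At oxygen 1 they included autophagy (-0.058; 0.362), interferon-stimulated genes (-0.060; 0.719), antigen presentation (-0.073; 0.394) and macrophage identity (-0.062; 0.233), and when starved inflammatory cytokines (-0.11; 0.345), macrophage identity (-0.070; 0.394) and neutrophil markers (-0.19; 0.464). Averaged they included autophagy (-0.031; 0.362), inflammatory cytokines (-0.026; 0.394), interferon-stimulated genes (-0.038; 0.719) and stromal markers (-0.082; 0.400). Of the 29 calls 19 were lost without at least 1 single sample and 10 with slide as a block. Adjusted over the list alone, Lyz2 also passed in each condition.

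**Figure D3:**
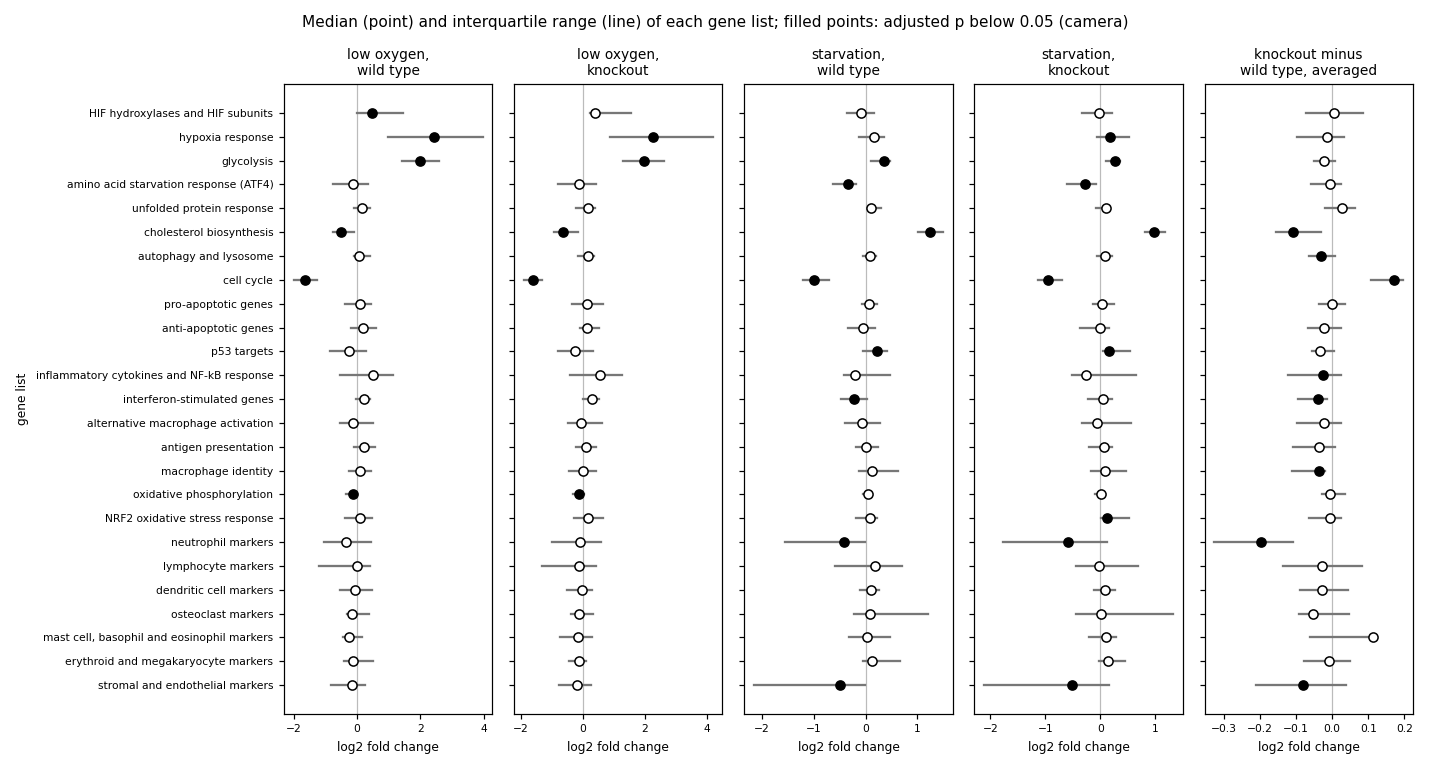
Median log2 fold change (x axis, with scales that differ between panels) of each gene list (y axis) in the comparisons shown above each panel; points are medians, grey lines the interquartile range of the list's genes, and filled points passed camera's adjusted p of 0.05. The hypoxia response sits at 2.45 and 2.25 at oxygen 1 in wild type and knockout, and the averaged genotype medians lie between -0.20 and 0.17.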

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

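The differences in this part came from tests of the interaction itself, and none of these tests was chosen after the result was seen. Dixon's test for a single outlying sample was not run, since each group held 3 samples. A total of 3 samples stood apart on the first principal component of the deviations from the group means (0.38 for replicate 1 of the wild-type controls, 0.44 for replicate 3 of the knockout controls and 0.40 for replicate 3 of the starved wild-type cells), and these were left out together in a fit added after the data were seen. Each sample was also left out in turn.

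A total of 5 list tests of a difference between the responses of knockout and wild-type cells passed camera at the preset correlation, and none of them held with an estimated correlation. Limma called 0 genes in the interaction with low oxygen and 0 in that with starvation, with 243 and 213 at an unadjusted p below 0.05. In the response to starvation the cholesterol biosynthesis list was lower in the knockout by a median of -0.28 (adjusted p = 4.90e-07; adjusted p = 0.438 with an estimated correlation; -0.27 with slide as a block). It was -0.092 and -0.47 without replicate 1 or 2 of the starved knockout samples and -0.15 without replicate 1 of the starved wild-type samples. The interferon-stimulated genes were higher by 0.21 (adjusted p = 1.62e-11; adjusted p = 0.362 with an estimated correlation; 0.19 with the block), but by 0.14 without replicate 1 of the starved knockout samples, 0.33 without replicate 1 of the wild-type controls and 0.33 without the 3 samples. The hypoxia response was higher by 0.077 (adjusted p = 1.54e-04; adjusted p = 0.155 with an estimated correlation; 0.097 with the block), and by 0.13 without replicate 3 of the knockout controls, 0.16 without replicate 3 of the starved knockout samples, 0.14 without replicate 2 of the wild-type controls, 0.14 without replicate 1 or 3 of the starved wild-type samples, and 0.13 with normexp and quantile normalization. NRF2 targets were higher by 0.15 (adjusted p = 3.42e-04; adjusted p = 0.592 with an estimated correlation; 0.15 with the block), a difference that was 0.0096 without replicate 1 of the starved knockout samples (adjusted p = 0.595), 0.096 without replicate 1 of the wild-type controls, 0.050 without replicate 3 of the starved wild-type samples and 0.087 without the 3 samples. In the response to low oxygen the cholesterol list was lower by -0.10 (adjusted p = 0.0278; adjusted p = 0.765 with an estimated correlation; -0.040 with slide as a block). A total of 13 of 21 alternatives ended that call, 7 of them by leaving out a single sample. It was -0.19, -0.068 and -0.093 without replicate 1, 2 or 3 of the knockout samples at oxygen 1, -0.077 without replicate 3 of the knockout controls, 8.0e-04, -0.24 and -0.071 without replicate 1, 2 or 3 of the wild-type samples at oxygen 1, and -0.14, -0.16 and -0.11 without replicate 1, 2 or 3 of the wild-type controls. The hypoxia response did not pass in this interaction (median 0.095, adjusted p = 0.0799), but passed under 3 of 21 alternatives, with adjusted p between 0.00454 and 0.543. None of the 5 calls held with fry.

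Regrouping the genotype labels within conditions gave as many called genes in 100 of 100 groupings for the interaction with low oxygen and in 100 of 100 for that with starvation, since the real count was 0 in both. Of the 99 other groupings 6 and 5 called any gene, and the highest called 28 and 89, as a structure among the samples would give, which was not tested further.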

How the results depend on the processing

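The normexp settings and the fit without the 3 samples that stood apart were chosen after the data were seen. Of 233 named gene results past the threshold 161 kept direction and threshold under every setting and 72 lost the threshold under at least 1, and of 152 not past it 4 passed under at least 1. Normexp with percentile scaling called 3909 and 4221 genes at low oxygen, 1128 and 898 under starvation (wild type, knockout) and 3 between genotypes on average, and turned Ndufa4l2 in starved wild-type cells to 0.34 and the 1 transcript called higher in the knockout to a lower value; the cause was not tested. A 2-fold threshold called 2611, 2762, 851, 868 and 2, and an adjusted p below 0.01 1424 and 1511 under starvation and 3 between genotypes, as stricter thresholds must. Between genotypes on average, the authors' value table, the mean of probes and slide as a block called 3 genes each and the first array 2; when starved, quantile normalization called 2, the replicate block 1 and the intensity trend 1; the cause was not tested. Egln3 averaged -0.12 without the 3 samples. With an estimated correlation 4 of 62 list tests held, and with fry 25, while fry called 26 others.

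Leaving out 1 sample gave 6628 to 7506 and 6955 to 8154 genes at low oxygen, 1664 to 2552 and 2001 to 2210 under starvation, 0 to 0, 0 to 1 and 0 to 2 between genotypes in controls, at oxygen 1 and when starved, 4 to 6 on average, 0 to 1 and 0 to 0 for the interactions, -0.26 to -0.15 for Egln3 and 56 to 69 list calls. The interferon list between starved genotypes ranged from -0.028 to 0.14. The 1664 came without replicate 1 of starved wild-type cells. A gene was called without knockout replicate 3 or wild-type replicate 1 or 3 at oxygen 1, without knockout starved replicate 2 or 3, and, for the low-oxygen interaction, without knockout control replicate 2.

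Samples with one number within a genotype correlated over 0.1 in 8 of 18 pairs (-0.087 to 0.29), so the numbers were not taken to pair the samples. A hint of pairing in the data is that 13 of 18 samples were closest to their own number, that the median correlation was 0.078 for the same number and -0.053 for different ones, and that the 3 knockout pairs of oxygen 1 with starvation lay over 0.1 (0.15, 0.18 and 0.16). The replicate block kept all 62 list calls, ended 5 of 233 named gene calls and called 4 genes in the averaged genotype comparison, against 5 without it. For genotype in a single condition it joined wild-type and knockout samples of one number. Genes near background limited the folds that could be given.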

Other observations

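The tests of Lyz2, of the Egln3 probe position and of stromal-cell loss in this part were chosen after the result was seen, and so were the genes named in the next 2 paragraphs, which were chosen after their values were seen. The directions given for those genes were the same under each scaling tried.

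Single inflammatory genes changed in both directions, while the inflammatory list did not pass camera in wild type at oxygen 1 (adjusted p = 0.130) or when starved (0.300). At oxygen 1 the nitric oxide synthase Nos2 was 16.9-fold and 23.1-fold higher in wild type and knockout, the prostaglandin synthase Ptgs2 9.41-fold and 15.6-fold and the cytokine Il1b 7.75-fold and 10.1-fold, and Il6 2.13-fold and 2.38-fold and the chemokine Cxcl2 1.58-fold and 1.56-fold higher. Tnf was 2.17-fold and 2.54-fold lower there, and the chemokine Ccl2 changed by -0.77 and -0.46 on the log2 scale (adjusted p = 0.0103 and 0.107). In starved cells the interleukin 1 antagonist Il1rn was 5.42-fold and 6.03-fold higher and Ccl2 2.58-fold and 2.49-fold higher, while Cxcl2 was 2.88-fold and 3.23-fold lower and Il6 1.82-fold and 2.13-fold lower.

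The osteoclast and antigen presentation lists did not pass camera in wild type at oxygen 1 (adjusted p = 0.959 and 0.310) or when starved (0.0549 and 0.788), but some of their members changed. The protease Ctsk was 7.27-fold and 8.31-fold higher at oxygen 1 and 4.21-fold and 5.80-fold higher in starved cells, and the integrin Itgb3 5.28-fold and 4.38-fold higher in starved cells. At oxygen 1 the class II gene H2-Ab1 was 15.4-fold and 15.2-fold higher and the invariant chain Cd74 2.92-fold and 3.45-fold higher, while H2-Eb1 changed by -0.81 and -0.83 on the log2 scale and H2-Aa was lower (adjusted p = 0.0499 and 0.0127), with a signal not well above background at oxygen 1 and no fold for that reason. The log2 change of H2-Aa lay between -1.26 and -0.087 and between -1.71 and -0.17 over the scalings, so its fall depended on them. The efferocytosis receptor Mertk was 3.50-fold and 4.50-fold lower there.

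Lyz2 was lower in every knockout group. A candidate explanation is that 1 of the 2 copies of Lyz2 carries an insertion in the samples labelled knockout, as in the LysM-Cre line often used to delete genes in macrophages, which would give a log2 difference of -1; the averaged difference was -1.02 (95% interval -1.23 to -0.82), and the labels used here do not describe the allele. The other 30 macrophage identity genes had a median of -0.036 (quartiles -0.11 to -0.017), which argues against a lower share of macrophages, and with slide as a block Lyz2 stood at -1.08 (-1.29 to -0.87), which argues against a difference between slides. The related gene Lyz1 differed by -0.10 (-0.32 to 0.11). A biological effect of PHD3 on Lyz2 was not tested and stays open.

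The Egln3 signal of the samples labelled knockout was close to that of wild type. Of 100 groupings of genotype labels within conditions, only the real one gave a p as small as its smallest, that of Lyz2. The labels thus tracked Lyz2, which does not show whether Egln3 is deleted. Whether both probes lie outside the deleted part, with the remaining transcript still made, cannot be told apart from other causes, because probe sequences and the allele were not used here; the difference at oxygen 1 was -0.038.

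The stromal list was lower in the starved samples (median -0.50 and -0.52), and the contractile genes Myl9, Actg2 and Cnn1, which were in none of the lists, fell. Of 6 collagen and proteoglycan genes, Col1a1 (-3.41 and -3.52 in wild type and knockout) and Col1a2 (-2.67 and -2.80) fell most. The other 4 lay over 1 log2 unit above Col1a1 in both genotypes. Col6a1 read -0.87 and -0.67 (intervals below 0), Col3a1 -0.53 and -0.52 and Bgn -0.21 and -0.19 (including 0), and Dcn 0.74 and 0.33. This argues against fewer stromal cells as the whole cause. The stromal list had a highest within-slide median of -0.12, below 0 on every slide that held both groups, which argues against a difference between slides. Lower activity of serum-responsive (SRF and YAP) target genes could not be decided: 19 of 24 listed targets were measured, with medians of -0.11 and -0.14, 2 rising and 1 falling in wild type and 2 rising and 3 falling in the knockout.

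Other splits of the samples called fewer genes than low oxygen and starvation did. Each of those splits mixed treated and control samples, so the treatment effect entered its spread and lowered its count. The low counts therefore give no chance level for the real ones. In 1 of the 10 splits of the 6 samples, the real one, as many genes were called for low oxygen in wild type (8037, highest other 1) and in the knockout (8290, highest other 0), and for starvation in wild type (2596, highest other 1) and in the knockout (2791, highest other 1). Between genotypes 10 of 10 splits called as many as the real 0 in controls (limma, 284 at an unadjusted p below 0.05; highest other 1), at oxygen 1 (365; highest other 21) and when starved (393; highest other 1). A total of 10 splits are too few for a share under 0.05. For the averaged genotype comparison 2 of 100 groupings, the real one included, called at least the real 5 genes. These groupings treated the samples as independent. Whether samples with one number come from one mouse is not given, so chance was not excluded for that count. Groupings were not counted under the alternatives, which called between 2 and 6 genes. Of the 99 others 3 called any gene, and the highest called 29, several times the real count, as a structure among the samples would give.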
